A study of Mus musculus with 4 samples.

How the data were processed

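Total RNA from area CA1 of the hippocampus was measured on 4 Affymetrix mouse arrays, 1 for each of 4 control samples of young male C57BL/6J mice. The samples were grouped by the hour in their titles, 1, 2, 4 or 6 h, with 1 sample per hour. How many mice gave RNA to a sample, when the arrays were run, and what the ordinal number in the sample titles stands for are not stated in the sources used here. No batch could therefore be tested.

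The deposited values are 1 intensity per probe set and array on a linear scale. The software that made them from the scanned arrays is not given in the sources used here, and the table used here carries no detection calls. After removal of 2% of the values at each end, the mean of each of the 4 arrays was 500.3, and these means differed by 0.0062% at most. The authors therefore appear to have scaled each array to one mean. Such scaling leaves differences in the shape of the signal distribution between arrays in place. A signal is comparable between arrays for the same probe set only, since probe sets differ in how strongly they bind. No 2 of the arrays held identical values.

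The values were used as deposited, because the rule fixed beforehand was to normalize only if those trimmed means differed by over 10%. Values under the pooled 20th percentile, a signal of 36.8, were set to it, and log2 was taken. Of 12488 probe sets, 66 were manufacturer controls, used as quality measures only. The 7237 probe sets whose mean log2 over the 4 arrays reached the pooled 40th percentile, a signal of 116.4, were tested. Gene symbols came from the platform's annotation table. They were updated through gene identifiers for 10817 of the 10833 probe sets with 1 symbol, and 16 had no match. Another 396 probe sets had several symbols and 1193 had none, and none of these is named. Genomic coordinates are not given, since the values carry no genome build. A gene with several probe sets entered a gene list through the probe set with the highest mean, which left 5546 genes. Of the tested probe sets, 1393 have a name ending that marks probes shared between transcripts or an incomplete probe set.

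A trend over time was tested with limma as the slope of log2 signal per hour over all 4 arrays, with 2 residual degrees of freedom, a mean-dependent variance prior, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. The 2, 4 and 6 h arrays were each set against the 1 h array with no test, by counting probe sets at least 2-fold apart. In all, 30 gene lists were fixed, covering immediate early, clock, glucocorticoid, synaptic, metabolic and stress genes and markers of the cell types and neighbouring regions that a CA1 dissection could hold. The 29 lists with 5 or more measured genes were tested for a trend with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. For single arrays, the median log2 difference of a list was given as a percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. This percentile describes the arrays compared and is not a test. Lists below the 2.5th or above the 97.5th percentile were counted as standing outside the central 95%.

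The genes named were those with 1 symbol and both values of the comparison above the floor that had the 10 highest and the 10 lowest slopes, or the 10 largest differences each way for each hour against 1 h, taken in rank order. In each list, the 2 measured members with the largest difference either way between 6 h and 1 h were added, together with a fixed set of immediate early, clock, glucocorticoid and NF-kappaB genes and of tissue markers. The other list members named, the control transcripts apart from Gapdh and beta-actin, and the probe sets far from all 3 other arrays were chosen after their values were seen. The groups, lists, tests, filters and most alternatives were fixed before the data were examined. Alternatives covered normalization, floor, filter, probe sets used, time scale, variance prior, fold threshold, reference array, list test and leaving out each array in turn.

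The steps were tested on simulated data. Over 7237 simulated probe sets with the spread of the real ones, the limma slope test found 0% of probe sets given a slope of 0.2 log2 per hour, 11.9% of those given 0.4 and 45.5% of those given 0.8, and called 0% of the unchanged ones. Lists of 20 genes given a slope of 0.2, among 5546 genes, were found in 100% of 20 simulations by camera at an unadjusted p of 0.05 and by the random-list percentile, and camera called 5% of the unchanged lists. The simulated genes varied independently of each other, so these rates do not cover lists whose members vary together. They also do not cover shorter lists or slopes as shallow as those of the real lists. The steepest median slope of a real list was -0.0977 log2 per hour, for CA3 markers. The number of arrays limits the precision of every value. The analysis used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.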

Results

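The series held 4 samples of total RNA from area CA1 of the hippocampus, a region of pyramidal neurons needed for contextual memory, taken from young male mice of the inbred strain C57BL/6J. All 4 were controls: the mice had been handled by an experimenter and received nothing else. Their RNA was taken 1, 2, 4 and 6 h after the last shock given to treated mice, which are not analysed here. The comparisons ask which CA1 transcripts differed between control samples over these hours. Each hour had 1 sample on 1 array, so no difference between 2 hours has a replicate check. Signals are the authors' scaled probe set intensities, given per array or as the mean ± SD over the 4 arrays.

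Transcripts of neurons and glia were measured on every array. Snap25, a component of the synaptic fusion machinery, had a signal of 18884 ± 858 (SD, n = 4), and Gad1, which makes GABA in interneurons, had 4272 ± 180 (SD, n = 4). The CA1 pyramidal marker Wfs1 had 2290.5 ± 292 (SD, n = 4), and the myelin gene Mbp had 8127 ± 852 (SD, n = 4) on its brighter probe set. Prox1, a marker of dentate granule cells, gave 57.9 at 1 h and 12.5, 17.8 and 18.2 at 2, 4 and 6 h, the last 3 under the floor of 36.8. Hba-a1, a haemoglobin gene that reports blood left in the tissue, had 2539 ± 390 (SD, n = 4). Ttr, the most abundant transcript of the choroid plexus, varied more, with signals of 222, 892, 108 and 356 at 1, 2, 4 and 6 h. The Y-linked gene Eif2s3y gave 160, 173, 142 and 199 on the 1 tested probe set of the sex-linked list.

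The 1, 4 and 6 h arrays resembled each other, and the 2 h array stood apart. Of 7237 probe sets, 46.4% stayed within a 1.5-fold range over the 4 arrays, 77.4% within 2-fold, and 4.56% ranged over at least 4-fold. Across probe sets, the SD of the log2 difference was 0.54 for 4 h against 1 h, 0.54 for 6 h against 1 h and 0.55 for 6 h against 4 h. Pairs with the 2 h array had SDs of 0.66, 0.62 and 0.65 against 1, 4 and 6 h. The gap was wider among the 2412 brightest probe sets, where the SD was 0.49 for 2 h against 1 h but 0.30 for 4 h and 0.27 for 6 h against 1 h. In this bright group 4.93%, 0.58% and 0.33% of probe sets lay at least 2-fold from the 1 h array at 2, 4 and 6 h. Gapdh and beta-actin were also less 3'-weighted at 2 h. This sets the 2 h array apart but does not show that it, rather than the others, is the faulty one. The 3' over 5' signal ratio of Gapdh, a glycolytic enzyme used as an RNA quality control, was 1.08 at 2 h against 4.10, 3.62 and 3.95 at 1, 4 and 6 h. The ratio of beta-actin was 1.72 at 2 h against 2.27, 2.59 and 2.93, while that of ribosomal 18S RNA was 6.41 at 2 h against 4.85, 3.34 and 6.11. The 9 spike-in control probe sets gave 0.724 times their mean over arrays at 2 h and between 1.05 and 1.16 times on the other arrays.

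**Figure D1:**
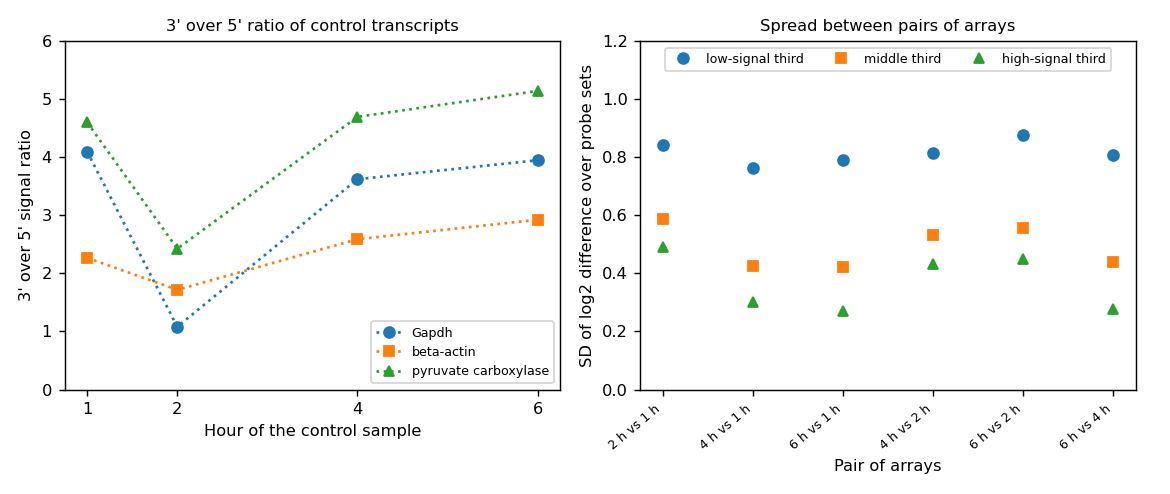
Left, the 3' over 5' signal ratio (no unit) of 3 control transcripts, Gapdh, beta-actin and pyruvate carboxylase, on the arrays of 1, 2, 4 and 6 h. Right, the SD over probe sets of the log2 difference for each pair of arrays, in 3 groups of probe sets by mean signal. The 2 h array has the lowest ratio for each of these 3 (Gapdh 1.08), and bright probe sets spread more in pairs that include it (0.49 against 0.27 for 6 h against 1 h).

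Among probe sets with 1 gene symbol and signals above the floor on all 4 arrays, the steepest upward slope was that of Acsm2, an acyl-CoA synthetase, and the steepest downward one that of Cpsf4, a factor of mRNA 3' end processing. Acsm2 had signals of 42.3, 102, 208 and 360, a slope of 0.59 ± 0.13 log2 per hour (SE, 4 arrays). The dimmest tested probe set of Gstm5, a glutathione transferase, followed with 0.46 ± 0.20, then Ifna9, an interferon, with 0.46 ± 0.13, the dimmer probe set of Prss32, a serine protease, with 0.46 ± 0.16, and Epor, the erythropoietin receptor, with 0.45 ± 0.14. Brighter probe sets had slopes of 0.02 and 0.05 for Gstm5 and 0.02 for Prss32. Cpsf4 had signals of 357, 211, 57.3 and 48.7, a slope of -0.61 ± 0.15. Next came the dimmest probe set of Pdia6, a protein disulfide isomerase, with -0.55 ± 0.16 (0.05 on the brightest and -0.48 on the third), Spr, sepiapterin reductase, with -0.55 ± 0.16, 1810021B22Rik with -0.51 ± 0.14, and Calb2, the interneuron calcium buffer calretinin, with -0.51 ± 0.12. All of the 10 steep slopes came from probe sets with a signal under 73.6 on at least 1 array, within 2-fold of the floor.

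None of these slopes passed: limma called 0 of 7237 probe sets, with a smallest adjusted p of 0.9996. At an unadjusted p under 0.05 there were 196, of which 85 sloped up and 111 down, against the 362 that chance gives. Leaving out the 2 h array gave 32 calls, 22 up and 10 down, from 1 residual degree of freedom, and leaving out any other array gave 0. Without the 2 h array limma's prior degrees of freedom were infinite, so a spread shared between probe sets replaced each one's own. They were 5.79, 7.62 and 6.18 without the 1, 4 and 6 h arrays, so the 32 calls cannot be set beside the 0 of those fits. Among the 32, the 1 h array was the lowest of the 4 in 22, and the 2 h value lay at least 2-fold off the line in 15. The 32 included the synaptic genes Chrna7, a nicotinic acetylcholine receptor subunit (58.3, 439, 271 and 384), and Grik5, a kainate receptor subunit, on its dimmer probe set (71.3, 450, 359 and 441) but not on its brighter one (377, 1294, 554 and 389).

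Gene lists showed no trend past the threshold either. The genes of cholesterol synthesis came nearest, with a median slope of -0.06 log2 per hour over 12 genes: camera gave p = 0.00637 and adjusted p = 0.185, and adjusted p = 0.968 with an estimated correlation. Squalene epoxidase, Sqle, had signals of 952, 1218, 712 and 564, and squalene synthase, Fdft1, had 956, 1001, 1011 and 558. Camera called 0 of 29 lists, with 1 at an unadjusted p under 0.05, and fry called 0 with 0 at that p. Without the 1 h array, camera at its preset correlation called 3 lists, all downward from 2 to 6 h: thalamus and habenula markers and glutamate receptor genes (adjusted p = 0.045 each by camera) and CA3 markers (adjusted p = 0.0498). With an estimated correlation camera called 0, each of the 3 at an adjusted p of 0.894. Without the 2 h array camera called 0 lists at either setting. Calb2, with signals of 352.5, 329.5, 94.4 and 73.5, was called by limma when adjusted over the list alone, with an adjusted p of 0.0396 among thalamus and habenula markers but 0.0719 among interneuron markers. In the remaining lists limma called 0 genes when adjusted over the list alone.

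Among probe sets with 1 gene symbol, those farthest above 1 h at 2 h had signals over 8 times as high, but the brighter probe sets of 4 of these genes did not repeat this. Mid1ip1, a regulator of lipid synthesis, had 695 against 38.0 on its dimmer probe set but 1735.5 against 1565 on its brighter one. Chrm1, the main muscarinic receptor of the hippocampus, had 704 against 45.4, and Rnf112, a neuronal ubiquitin ligase, had 582 against 42.0. The probe sets of Nsmf, which carries NMDA receptor signals to the nucleus, disagreed, with 2041 against 151 on the dimmer and 497 against 1090 on the brighter, log2 differences of 3.76 and -1.13. Ube2h, a ubiquitin-conjugating enzyme, had 881 against 75.5 on its dimmer probe set, while its brighter one was 1.59 times as high at 2 h, and Lmo2, a transcription regulator, had 382 against 38.2 on the dimmer and 430 against 349 on the brighter. Arnt2, a partner of activity-regulated transcription factors, had 426.5 against 44.5, and Kif5a, a kinesin of axonal transport, had 2420 against 260 and then 286 and 233. The lowest at 2 h against 1 h were Thoc7, an mRNA export factor, with 45.4 against 287.5, Sdf2 with 63.4 against 376, the transcription factor Hand1 with 131 against 655, and Aanat, which catalyses a step of melatonin synthesis, with 146 against 667. Of the 20 probe sets so ranked, 11 had a lower value under 73.6, against 1.66% of all probe sets compared. In all, 501 probe sets were at least 2-fold higher and 238 at least 2-fold lower at 2 h. With a stricter filter on dim probe sets, the counts of both directions together were 304, 76 and 74 at 2, 4 and 6 h in place of 739, 449 and 473. The 2 h array had 149 probe sets at least 2-fold above and 77 at least 2-fold below each other array.

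Lists of synaptic signalling genes had medians above 0 at 2 h. Outside the central 95% of random lists lay 5 of 29 lists. Lists of genes that vary independently would put 1.45 there. Genes of a list that vary together could put more, so the count of 5 is not by itself an excess over chance. The count depended on the filter on dim probe sets, and more lists lay outside without it. Glutamate receptor and postsynaptic density genes had a median log2 difference of 0.56, at percentile 99.89 of random lists, with 10 of 12 genes higher and 3 at least 2-fold higher. The kainate receptor gene Grik5 had 1294 against 377 on its brighter probe set, the AMPA receptor gene Gria3 had 585 against 237, and the NMDA receptor gene Grin2b had 459 against 79.5, whereas neurogranin, Nrgn, had 3735 against 5620. Among 19 genes of synaptic vesicles and release, with a median of 0.26 at percentile 99.70, 10 were higher and 9 were not, and 5 were at least 2-fold higher. Synaptotagmin 1, Syt1, had 3671 against 722, complexin 1, Cplx1, had 4088 against 1139, and synaptophysin, Syp, had 1679 against 758, while Snap25 and the brighter probe set of Vamp2 stayed within 1.2-fold (837 against 197 on the dimmer). GABA receptor, synthesis and transport genes had a median of 0.41 over 9 genes, 6 of them higher, at percentile 98.23, with Gabra2 at 1164 against 687 but the vesicular GABA transporter Slc32a1 at 2019 against 3861. That place outside the central 95% was lost with a stricter filter (percentile 73.76) or with another floor (93.73 and 93.85). These groups stood high on the array with the lowest 3' over 5' ratio of Gapdh (1.08).

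Glycolysis genes and chaperones also stood high at 2 h, on the array that stood apart and had the lowest 3' over 5' ratio of Gapdh (1.08 against 3.62 to 4.10). Glycolysis genes had a median log2 difference of 0.23 over 15 genes, at percentile 99.06, with 12 higher. The phosphofructokinase gene Pfkm had 3456 against 832 and the lactate dehydrogenase gene Ldhb had 2817 against 1565, whereas hexokinase 1, Hk1, had 4730 against 6034. Heat shock proteins and chaperones had 0.19 over 33 genes, at percentile 99.23 but 96.44 after quantile normalization, with 22 higher. The inducible Hspa1a had 854 against 425 and its neighbour Hspa1b had 418 against 295. No list stood below the central 95% at 2 h. Oxidative phosphorylation genes had a median of -0.24 at percentile 5.24, with 11 of 43 higher.

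Immediate early genes, which neuronal activity induces within minutes, were mixed at 2 h. Their median was 0.16 over 26 genes, at percentile 92.88, with 16 higher and 3 at least 2-fold higher. With all probe sets of a gene averaged the percentile was 99.03, and without the filter on dim probe sets 98.36. Fos had 292, 574, 413 and 271 at 1, 2, 4 and 6 h, but 74.7, 52.8, 136 and 54.6 on a second probe set too dim to test. Nr4a2 had 426, 1123, 406 and 274, and its second probe set had 293, 736, 474 and 232. Egr2 had 184, 419, 192 and 108, and Dusp6, a phosphatase of ERK kinases, had 760, 1606, 930 and 825, but 85.7, 63.1, 65.4 and 131 on a second one as dim. Egr1 varied less, with 2073 ± 323 (SD, n = 4). The probe sets of Junb disagreed at 2 h against 1 h, with 662 against 187 on one and 490 against 523 on the other. NF-kappaB genes had a median of 0.07 over 11 genes, at percentile 64.15, which turned to -0.00092 when arrays were centred on their medians. Their inhibitor Nfkbia had 779 ± 54.0 (SD, n = 4) on its brighter probe set, and Rel, with signals of 8.4 to 37.8, was too dim to test.

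Clock genes did not move one way, with a median of -0.10 over 16 genes at percentile 27.88. At 2 h against 1 h 2 were at least 2-fold higher, 3 at least 2-fold lower and 11 within 2-fold. The period gene Per1 had 270, 642, 408 and 389, and the cryptochrome gene Cry2 had 116, 592, 179 and 191. The output gene Dbp had 621, 285, 520 and 575, the nuclear receptor gene Nr1d1 had 706, 282, 792 and 609, and Usp2, a clock-controlled deubiquitinase, had 1875, 846, 2115 and 2031, with 1721, 1017, 1949 and 1947 on its second probe set. Glucocorticoid-responsive genes had a median of -0.03 over 22 genes, at percentile 50.26. Of these, Tsc22d3 had 166, 42.9, 136 and 192, Sgk1 had 963, 732, 645 and 763, and Fkbp5, the feedback regulator of the glucocorticoid receptor, had 787, 1146, 1058 and 1108. None of these genes passed limma's trend test (smallest adjusted p of 0.9996 over all genes). That test fits a straight line over the hours, so it cannot judge a rise or fall at 2 h alone. Cry2, for example, had a slope of -0.03 log2 per hour. The 2 h values come from the 1 array that stood apart and had the lowest 3' over 5' ratio of Gapdh (1.08). Whether its 3' weighting moved these genes was not tested. The 2 h signal of Tsc22d3 (42.9) lies within 2-fold of the floor of 36.8. The hour of day at sampling is not stated.

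**Figure D2:**
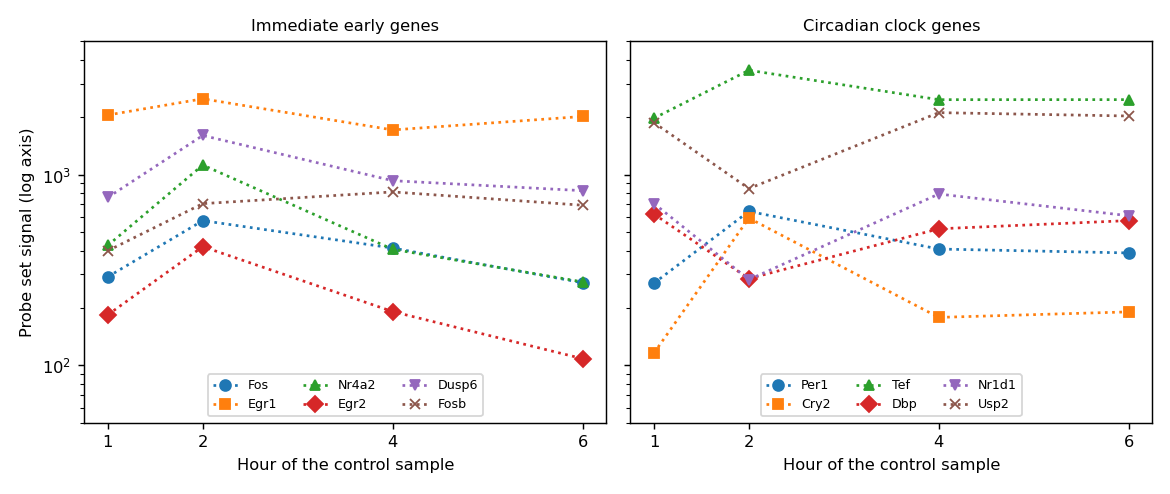
Probe set signal (log axis) of 6 immediate early genes (left) and 6 clock genes (right), on the brightest probe set of each, on the control arrays of 1, 2, 4 and 6 h, 1 array per hour, joined by dotted lines. Nr4a2 is highest at 2 h (1123), where Dbp (285) and Nr1d1 (282) are lowest. Several of the genes shown were chosen after their values were seen. At 2 h, 23 of 26 immediate early genes and 11 of 16 clock genes stayed within 2-fold of 1 h. Dimmer probe sets of Fos and Dusp6 that disagree are not shown.

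Markers of other regions and cell types spread widely at 2 h, and none of these lists lay outside the central 95%. Near its upper end were oligodendrocyte (percentile 96.46), CA3 (96.11), choroid plexus and ependyma (95.53) and thalamus and habenula markers (93.86). Dentate gyrus markers (5.61) were near its lower end. Choroid plexus and ependyma markers had a median of 0.50 over 6 genes, led by Ttr (892 against 222) and Igfbp2 (711 against 317). Thalamus and habenula markers had 0.40 over 11 genes, with Ramp3 at 410 against 57.4, CA3 markers had 0.38 over 6, oligodendrocyte markers 0.21 over 12, meningeal markers 0.18 over 11, microglial markers 0.15 over 12 and CA1 pyramidal markers 0.11 over 7. Medians below 0 were found for dentate gyrus markers (-0.37 over 6), striatum markers (-0.34 over 5), blood markers (-0.16 over 5), interneuron markers (-0.14 over 20), astrocyte markers (-0.13 over 16) and endothelial markers (-0.00029 over 13). Some lists share members: Grik5 is in both the CA3 and the glutamate receptor lists. Cplx1, which was also higher at 2 h, is in both the thalamus and habenula and the synaptic vesicle lists. The remaining lists had medians of -0.17 for cytosolic ribosomal proteins, -0.13 for the proteasome, -0.14 for CREB and memory-related kinases, -0.02 for stress-signalling genes and 0.07 for cholesterol synthesis, the last turning to -0.00927 after quantile normalization and -0.00743 after median centring.

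At 4 h, the probe sets with 1 gene symbol farthest above 1 h were those of Gstm5, with 428 against 52.2 on its dimmest tested one, P2rx6, an ATP-gated channel subunit, with 509 against 70.9, Prss30 with 513 against 72.8, and Zbtb16, a zinc finger repressor, with 449 against 64.6 on its dimmer one. The brighter probe sets of these genes did not repeat this, with 2440 against 3124 and 15614 against 15084 for Gstm5 and 2366 against 2420.5 for Zbtb16. Those farthest below were Lsr, a lipoprotein receptor of tight junctions, with 48.8 against 335, Cpsf4 with 57.3 against 357, Dnaaf5 with 49.9 against 277, and the brain proteoglycan gene Bcan with 45.0 against 236, the last 2 on dimmer probe sets. The brighter ones had 232 against 260 for Dnaaf5 and 1366 against 1385.5 for Bcan. Of the 20 probe sets so ranked, 19 had a lower value under 73.6, within 2-fold of the floor, against 1.89% of all probe sets compared. There were 267 probe sets at least 2-fold higher and 182 at least 2-fold lower, or 208 and 237 after quantile normalization, and 101 and 167 when 4 h was set against the mean of the other 3 arrays.

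At 4 h 3 of 29 lists lay outside the central 95%, where lists of genes varying independently would put 1.45. Without the filter on dim probe sets the number fell below 1.45. Voltage-gated channel genes had the highest place, with a median log2 difference of 0.32 over 16 genes at percentile 99.64 and 12 higher. The calcium channel genes Cacna1b, with 740 against 365, and Cacna1a, with 267 against 175, and the potassium channel gene Kcnc1, with 299 against 157, were among them, while Cacna1g had 158 against 285. Synaptic vesicle genes had 0.18 at percentile 99.26, with 17 of 19 higher, among them Nsf at 10250 against 6213 and Rab3a at 724 against 458, and none 2-fold apart. Glutamate receptor genes had 0.26 at percentile 98.50, with 10 of 12 higher, and were at percentile 89.63 after quantile normalization. A floor at the 40th percentile took the channel genes to 94.78 and the glutamate receptor genes to 91.56. Set against each gene's mean over the 4 arrays, the median of the vesicle genes was -0.15 at 1 h and 0.01 at 4 h, and that of the glutamate receptor genes -0.19 and 0.01, while the channel genes had -0.03 and 0.13. The vesicle and glutamate receptor lists were thus lowest at 1 h. The 2 h array (0.11 and 0.28) is part of that mean, so their differences cannot be divided between the 1 h and 4 h arrays.

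At 6 h, the probe sets with 1 gene symbol farthest above 1 h were those of Acsm2, with 360 against 42.3, Gstm5 with 418 against 52.2, Lmo2 with 282.5 against 38.2, Faf1, a ubiquitin-binding factor, with 352 against 49.8, Znrf2 with 277 against 40.9, and Chrna7 with 384 against 58.3. Other tested probe sets of 4 of these genes differed less: 3159 against 3124 and 15607 against 15084 for Gstm5, 605.5 against 349 for Lmo2, 272 against 231.5 and 273 against 159 for Faf1, and 301 against 246 and 246 against 126 for Znrf2. Those farthest below were Cpsf4 with 48.7 against 357, the copine gene Cpne3 with 53.0 against 386, the surfactant gene Sftpc with 43.5 against 315, and Mob2, a kinase regulator, with 48.8 against 338. Here too 19 of the 20 probe sets so ranked had a lower value under 73.6, against 2.11% of all probe sets. There were 271 probe sets at least 2-fold higher and 202 at least 2-fold lower, or 215 and 247 after quantile normalization, and 137 and 222 against the mean of the other 3 arrays. Because 2, 4 and 6 h share the 1 h array, a low value at 1 h raises a probe set such as the dimmest of Gstm5 in all 3 comparisons. The 1 h array had 105 probe sets at least 2-fold below each other array and 5 above, the 4 h array 91 and 15, and the 6 h array 105 and 20.

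Cholesterol synthesis genes were the 1 list outside the central 95% at 6 h. Their median log2 difference was -0.25 over 12 genes, at percentile 2.01, with 8 of 12 lower. Lists of genes varying independently would put 1.45 of 29 outside. Besides Sqle and Fdft1, the sterol gene Sc5d had 124 against 191 (158 against 145 on its dimmer probe set) and Msmo1 had 612 against 785, while mevalonate kinase, Mvk, had 531 against 392.2 (65.1 against 139 on a probe set too dim to test). The list lay within the central 95% when all probe sets of a gene were averaged (percentile 5.17) or the floor was raised to the 40th percentile (9.19). Hspa1a and Hspa1b were both above 1 h at 6 h, with 929 against 425 and 619 against 295, in a chaperone list with a median of 0.09. Gadd45g, a stress and activity-induced gene, had 487 against 185, and Cdkn1a, the cell cycle inhibitor p21, had 157 against 345. Synaptic vesicle genes had a median of 0.11 at percentile 96.23, and Kcna1, a potassium channel gene of axons, had 699 against 1509.

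**Figure D3:**
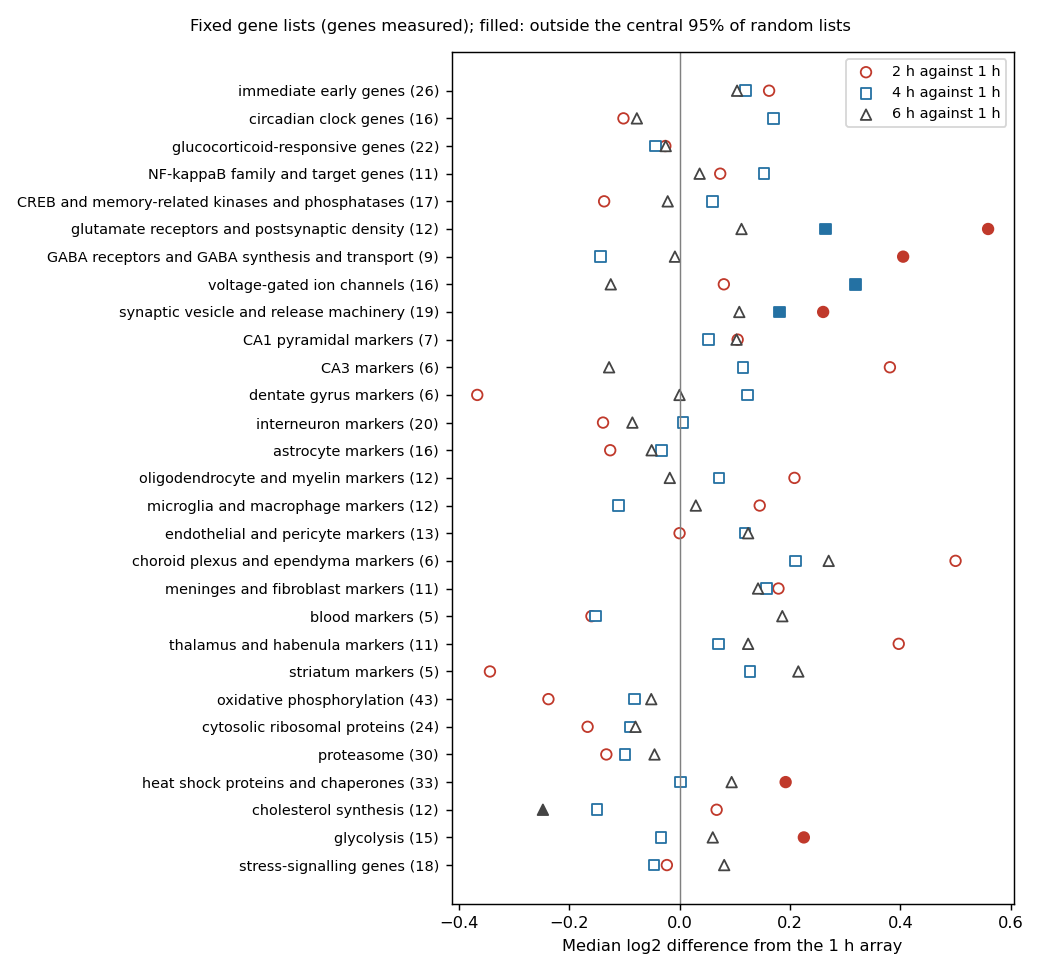
Median log2 difference from the 1 h array for 29 gene lists (number of genes measured in brackets), for the arrays of 2 h (circles), 4 h (squares) and 6 h (triangles), with filled symbols for lists outside the central 95% of random lists. The glutamate receptor list lies farthest to the right (0.56 at 2 h), and cholesterol synthesis at 6 h (-0.25) is the 1 filled symbol left of 0.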

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

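The tests of 3' bias, of other tissue and of the immediate early genes were chosen only after those results had been seen, and the others before.

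The 3' over 5' signal ratio of Gapdh at 2 h, 1.08, lay far from the 4.10, 3.62 and 3.95 of the other arrays: its gap to the nearest was 0.844 of the whole range of values, more than Dixon's test at 95% allows for 4 samples. Chance marks about 1 in 20 such groups, and this was 1 of 9 array measures and 29 list levels examined.

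The 2 h array stood apart from the others, with SDs of 0.62 to 0.66 log2 against them. A target less weighted to the 3' end on that array is a candidate explanation that stays open. Of the 4 control transcripts the test needed, 3 had their lowest 3' over 5' ratio there, namely Gapdh, beta-actin and pyruvate carboxylase (2.43 against 4.60 to 5.15). The transferrin receptor had 2.55 at 2 h, with 5' signals under the floor of 36.8 at 1, 4 and 6 h. Its 3' signals there were 97.4, 160 and 133.1, so 5' signals at the floor would put each ratio above 2.55. The deposited 5' signals there were 29.7, 34.6 and 25.2. Such signals are dim and under the floor, so the test took no ratio from them and did not count this transcript. The ratios describe the target and do not show that it moved the other probe sets. Ribosomal 18S RNA, which lacks a poly(A) tail, did not follow, with 6.41 against 3.34 to 6.11. If position along the transcript decided the signal, probe sets of one gene should part on that array. Over 330 genes with 2 probe sets, their SD was 0.587 at 2 h (bootstrap 95% interval 0.532 to 0.639) and at most 0.486 elsewhere (up to 0.538), and the intervals overlapped. The same genes entered every array, so overlap of separate intervals does not test the difference. A noisier 2 h array would also raise this SD with no effect of position, so the question stays open. A difference between the mice sampled at 2 h and the others stays open and untested.

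The high place of glutamate receptor genes at 2 h was weighed next. A different distribution of signals on that array is argued against, since the list was at percentile 99.88 after quantile normalization, with a median of 0.52 instead of 0.56. More tissue of another region or cell type in the sample may have contributed and cannot be told apart from other sources. Of 12 other-tissue lists, choroid plexus and ependyma markers had the highest median, 0.50 against 0.559, with a bootstrap 95% interval of -0.989 to 1.07 for the difference, too wide to decide, where Ttr had 892 at 2 h and Igfbp2 is also a meningeal marker. The 3' weighting above, which was not tested on these genes for lack of probe positions, also stays open.

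The brighter probe sets of Fos, Nr4a2 and Dusp6 and the 1 of Egr2 were higher at 2 h than on the other arrays. Dim ones of Fos (52.8) and Dusp6 were lowest there, and the probe sets of Junb disagreed. A coordinated immediate early response in that sample could underlie the higher values. The list's median reached percentiles of 92.88 to 93.84 under 3 normalizations, within the central 95% but near its upper end, and 99.03 with all probe sets of a gene averaged, so neither a response nor its absence follows. Egr1 had 2500 against 1716 to 2055, and the array's different 3' weighting stays open here too.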

How the results depend on the processing

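The alternative that puts the mean of 4 h and 6 h in place of 2 h, the one that leaves the 2 h array out of floor and filter, and the other orders of the arrays were chosen after seeing the data. No paired analysis was possible because each hour has 1 sample.

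The count of probe sets with a limma trend was 0 under all alternatives of normalization, floor, filter, probe sets, time scale and variance prior, with 80 to 506 at an unadjusted p under 0.05 (196 as reported). Leaving out each array in turn gave 0 to 32 probe sets and 0 to 3 lists: 32 probe sets without the 2 h array and 3 lists without the 1 h array. The fit behind the 32 had infinite prior degrees of freedom, unlike the other fits, and why the lists changed was not tested. With an estimated correlation, chosen after seeing the data, camera called 0 lists without any 1 array. Of the 24 orders of the 4 arrays, 20 gave at least the 196 probe sets of the true order, and the highest other gave 921, so chance is not excluded.

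Without a filter on dim probe sets, 1735, 1574 and 1611 were at least 2-fold from 1 h at 2, 4 and 6 h (739, 449 and 473 as reported), and with a filter at the 60th percentile 304, 76 and 74, since more or fewer dim probe sets are compared. At 3-fold the counts were 241, 163 and 164 by construction. Against the mean of the other 3 arrays the 4 h count was 268, and the mean of 4 h and 6 h against 1 h gave 327. Lists outside the central 95% numbered 11 at 2 h and 1 at 4 h without the filter (5 and 3 as reported). At 6 h there were 2 with a floor at the 40th percentile and 0 with all probe sets of a gene averaged (1 as reported), and the cause was not tested. That floor equals the filter, so 12422 probe sets then passed the filter. In all, 70 such values stayed within 1.5 times the one reported and 17 did not. Values of named genes were compared under quantile normalization, median centring and floors at the 10th and 40th percentile only. Of these, 577 stayed: a slope if still not called, a difference if it moved by less than the SD over probe sets of similar signal. Another 51 moved by more. No slope and no difference of at least 2-fold reversed, and a change of sign in a smaller difference was not counted. Values as deposited are the setting used, so that alternative was not run. Quantile normalization and centring moved the median of all probe sets by less than 0.1 log2. Dim probe sets limit what can be seen: the SD between 1 h and 4 h was 0.76 log2 among the dimmest 2413 and 0.30 among the brightest 2412.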

Other observations

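These genes were chosen after their values were seen. Some transcripts set the 2 h array apart from all 3 others. Nnat, an imprinted gene of developing neurons, had signals of 931, 6529, 1180 and 980 at 1, 2, 4 and 6 h, the dimmer probe set of the long noncoding RNA gene Norad 490, 3106, 449 and 407.5 (17670, 12592, 18879 and 14974 on the brighter), and Atp6v0a1, a subunit of the vesicular proton pump, 342, 1835, 369 and 433. Syt11, a synaptotagmin, had 716, 3190, 832 and 804, and Arf3, a GTPase of the Golgi, 131, 852, 69.8 and 145 on its dimmest probe set and 1423, 5642, 2438 and 1849 on its brightest. Low at 2 h alone were the zinc finger gene Zkscan6 (200, 44.2, 242 and 277), the methyltransferase Smyd2 (698, 156.5, 718 and 518) and the repair gene Fancc (660, 159, 648.5 and 525).

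Memory-related kinases and phosphatases, a list with a median of -0.14, had members on both sides at 2 h against 1 h. The kinase genes Prkaca (2448 against 1401) and Prkar1b (8009 against 5054) and the calcineurin gene Ppp3cb (972 against 575) were higher, while Ppp3ca (8175 against 11159), Adcy8 (198 against 344) and the coactivator Crebbp (714 against 1598) were lower. The proteasome genes Psmd11 (1275 against 2330 on its brightest probe set, 336 against 181 on its dimmest) and Psmd3 (1343 against 528) also lay on opposite sides.

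Between 2 probe sets of the same gene, Pearson's r of the deviations from the other arrays across 330 genes was 0.138 (bootstrap 95% interval 0.0167 to 0.247) at 1 h, 0.139 (0.03 to 0.253) at 2 h, 0.0767 (-0.0378 to 0.191) at 4 h and -0.054 (-0.157 to 0.0569) at 6 h, where genes are not independent replicates. The intervals at 4 and 6 h include 0.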
